A study of Homo sapiens with 9 samples.

How the data were processed

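Total RNA of MCF7 cells was measured on 9 Affymetrix perfect-match-only expression arrays, 3 for each of DMSO, AF (1 µM, 8 h) and ONC1 (5 µM, 16 h). Groups and replicate numbers were taken from the sample titles, which call the replicates biological, and each array was one sample. The deposited values are log2 signals made with RMA, which corrects background, equalises the distribution of the arrays and summarises the probes of a probe set, per the submitters' processing notes. The version of RMA and the set of arrays normalised together were not given in the sources used here. RMA values are relative to the other arrays of the set, so a change shared by all transcripts is removed, and no detection calls were used. A group mean under 3.5, close to the arrays' medians, was treated as near background for named genes, a limit chosen after the data were seen. The values were used as deposited, without a further transformation, and their number of arrays limits the precision.

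Of 54715 probe sets, 102 control probe sets were left out. Of the others, 40914 carried exactly 1 gene symbol, 864 several and 12835 none. Gene numbers of 40858 named probe sets matched the reference annotation and those of 56 did not. The annotation, of assembly GRCh38.p14, was used only for gene names. Each of 19774 genes was represented by the probe set with the highest mean over all 9 arrays, and 10550 genes had more than 1 probe set. A named gene's change is that of this probe set, and its other probe sets did not always share it. No filter on dim probe sets was applied.

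Differential expression was tested with limma 3.58.1 in R 4.3.3. A linear model with 1 coefficient per group was fitted to all 9 arrays, contrasts were formed for AF against DMSO, ONC1 against DMSO and AF against ONC1, and variances were moderated with eBayes without a trend or robust option. P-values were two-sided and adjusted by Benjamini and Hochberg's method over the genes, and a gene was called at an adjusted p under 0.05. The fit had 6 residual degrees of freedom per gene and 3.36 prior degrees of freedom, a median residual SD of 0.17 on the log2 scale, and a median SE of 0.13. The family held 3 comparisons. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

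The 30 gene lists were AhR targets, NRF2 targets, p53 targets, integrated stress response, ER chaperones and unfolded protein response, heat shock response, immediate early genes, NF-kB targets, interferon-stimulated genes, oestrogen receptor targets, luminal epithelial identity, basal and mesenchymal markers, immune and endothelial markers, DNA replication, mitosis, homologous recombination and Fanconi anaemia repair, BCL2 family, RNA polymerase II and its CTD kinases, splicing factors, transcripts known to be short-lived, ribosome biogenesis, cytosolic ribosomal proteins, mitochondrial respiratory chain, cholesterol synthesis, hypoxia response, xenobiotic conjugation, Wnt and TGF-beta feedback genes, replication-dependent histones, small nucleolar RNAs and the zinc finger family. The last 3 were taken by the start of the symbol, which also brought in H1-10 and the antisense RNA ZNF790-AS1. Some genes, such as STC2 and ATF3, stand in several lists. Lists were tested with camera, which compares a list with the other genes, at its preset inter-gene correlation of 0.01, with adjustment over the 30 lists. Camera with an estimated correlation and fry were run beside it. The p-value of fry tests whether a list's genes move, on balance, one way, its mixed p-value tests change in either direction, and neither compares the list with other genes. Of the 13, 14 and 11 lists called in the 3 comparisons, 6, 10 and 6 held with an estimated correlation. In AF against DMSO these were NRF2 targets, p53 targets, mitosis, homologous recombination and Fanconi anaemia repair, the respiratory chain, and Wnt and TGF-beta feedback genes. Among the lists that lost their call with AF, the estimate ran from -0.0252 for basal and mesenchymal markers to 0.0517 for immediate early genes. Some of these estimates lay under the preset of 0.01, so a lost call need not mean correlated members.

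Named genes followed a rule. It took 10 of 11 genes of interest whatever their values, 1 being not used here. It added, for each compound against DMSO, the 10 genes with the largest positive and the 10 with the largest negative change among the called genes whose groups of arrays did not overlap, 6 and 6 for AF against ONC1, and 5 and 5 for genes changed the same way by both. In each list it took up to 4 members with the smallest p. Symbols of uncharacterised loci and of small or intergenic noncoding RNAs were left out of the ranked parts. Groups, the tests of the 3 comparisons, the lists, this rule and the alternatives were chosen before the data were examined, except those for genes that AF and ONC1 changed in opposite directions. The count of those genes, 6 examples of them, and the weighing of shared DMSO arrays and of dose and exposure time were chosen afterwards.

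The overlap of the AF and ONC1 responses was set against the count that independent lists give, and against 100 draws in which unchanged AF and ONC1 groups were simulated against shared DMSO arrays. The replicate numbers were not used as a block. Over the genes with a mean above the median gene's, same-numbered arrays of different groups had residual correlations from -0.0775 to 0.0164. Of 9 such pairs 0 exceeded 0.1. Alternatives were quantile normalisation, median centring, leaving out the dimmest genes (1 of every 3 by mean over all arrays), the mean over a gene's probe sets, every probe set tested on its own (54613), a fit of only the groups compared, replicate blocks, a trended and robust prior, array weights, an adjusted p under 0.01, a 2-fold minimum, the other list tests, and leaving out each array in turn.

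The scripts were tested on simulated data of 19774 genes, with 200 changed by AF, 200 by ONC1 and 396 different between them. The real data gave far more calls, and the call threshold depends on the share of changed genes. The recovery below therefore holds for the simulated setting only. For AF against DMSO 22.4% of simulated changes of 0.5, 85.1% of those of 1 and 100% of those of 2 on the log2 scale were recovered. The shares were 25.4%, 86.6% and 100% for ONC1 against DMSO, and 40%, 91% and 100% for AF against ONC1. Of 144, 145 and 324 calls, 6, 4 and 18 were of unchanged genes, and 0 genes were called in the wrong direction. Of 2 shifted lists of 20 genes for AF against DMSO 2 were found, and 0 unshifted lists were called.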

Results

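Gene expression was measured in MCF7 cells, an established oestrogen receptor positive human breast cancer line, after exposure to either of 2 small molecules or to the solvent. Aminoflavone (AF) is a ligand of the aryl hydrocarbon receptor (AhR), a transcription factor that switches on xenobiotic-metabolising enzymes, and was given at 1 µM for 8 h. Oncrasin-1 (ONC1) was given at 5 µM for 16 h. The control arrays are called DMSO in their sample titles, their treatment label reads None, and their exposure time was not given in the sources used here. A change against DMSO can therefore also hold an effect of exposure time. Each of the 3 groups held 3 biological replicates, 1 array each, so 9 arrays of total RNA in all. The arrays' medians lay between 2.95 and 3 on the log2 scale, and their 75th percentiles between 5.07 and 5.16 for DMSO, 4.94 and 4.96 for AF, and 4.85 and 4.94 for ONC1. Arrays of 1 group correlated between 0.991 and 0.995 across genes, AF arrays with DMSO arrays between 0.977 and 0.979, and ONC1 arrays with DMSO arrays between 0.966 and 0.969. The number of arrays, not a read depth, limits the precision. Changes below are log2 differences of group means with the standard error (SE) of limma's moderated fit, n = 3 arrays per group, and p-values are adjusted over 19774 genes unless a gene list is named.

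The first comparison asked what 8 h of AF did to these cells. CYP1A1, the classic AhR-induced cytochrome P450, was 21.7-fold higher than with DMSO (log2 4.44 ± 0.11 SE, adjusted p = 7.23e-08), and its log2 signal went from 6.84 ± 0.17 to 11.28 ± 0.06 (SD, n = 3). SERPINB5, which encodes maspin, rose by 4.67 ± 0.12 in log2 signal, from 2.86 to 7.54, and ATF3, a stress-induced transcription factor gene, by 4.50 ± 0.23, from 3.28 to 7.79. The DMSO signals of both genes cannot be told from background, so these are lower bounds on the change in transcript. GADD45A, a growth arrest gene, was 13.6-fold higher (3.76 ± 0.11), PMAIP1, which encodes the pro-apoptotic protein NOXA, 13.4-fold (3.74 ± 0.08) and CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, 5.62-fold (2.49 ± 0.09). ESR1, the oestrogen receptor gene, fell by 1.85 ± 0.09 and MYC fell by 0.98 ± 0.08 on the log2 scale. When every probe set was tested, the other probe set of CDKN1A (0.09), MYC (-0.01) and SERPINB5 (0.16) was not called with AF. Of the 8 ESR1 probe sets, 5 were called lower and 0 higher.

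The other large rises named by the rule were in DLX2 (3.66 ± 0.14), the long noncoding RNA NEAT1 (3.33 ± 0.16), GDF15 (3.10 ± 0.08) and RGS2 (2.42 ± 0.16). Of the 5 probe sets of NEAT1, 1 was called higher and 1 lower, and the GDF15 probe set is of a type that can cross-hybridise. The largest falls were in ZNRF3, a ubiquitin ligase that restrains Wnt signalling (-3.54 ± 0.25), ARID5B (-3.46 ± 0.18), SAMTOR (-3.41 ± 0.14), RAPGEF6 (-3.30 ± 0.23), RAPGEF2 (-3.29 ± 0.21), SRGAP1 (-3.13 ± 0.24), CHST15 (-3.10 ± 0.15), HYCC2 (-3.05 ± 0.20), ZSWIM6 (-2.98 ± 0.33) and CENPA, the centromeric histone H3 variant (-2.98 ± 0.13). All 20 of these genes had adjusted p-values of 1.90e-04 or lower, and the 3 AF arrays lay on one side of the 3 DMSO arrays for each. The other probe set of DLX2 (-0.03) and of CHST15 (-0.11) was not called when every probe set was tested. For ARID5B 2 of 5 were called (-3.46 to 0.01). The lower group's signal was under 3.5, near background, for DLX2, RGS2, ZNRF3, ARID5B, RAPGEF2 and ZSWIM6, and for ACER2 and RNF43 among the list members named for AF, so their differences are lower bounds in size.

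Among the AhR targets, 6 of 13 measured genes rose and 1 fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.000881 and adjusted p = 0.0548 with an estimated correlation). CYP1B1 rose by 1.87 ± 0.08 and TIPARP, an AhR-induced repressor of the receptor, by 1.47 ± 0.11. AHRR, the AhR repressor, differed by -0.03 ± 0.16 (adjusted p = 0.921). AHR itself fell by 0.68 ± 0.16 (adjusted p = 0.0124), a call that was lost without DMSO replicate 2 (-0.60, adjusted p = 0.052). NRF2 targets, the antioxidant genes, rose in 10 of 19 cases with no falls, and in 12 when adjusted over the list alone (camera adjusted p = 0.000135). Examples were HMOX1 (1.88 ± 0.14), the ferritin gene FTL (0.52 ± 0.08) and SLC7A11 (1.11 ± 0.12). Of 21 xenobiotic conjugation genes 6 rose, also when adjusted over the list alone, among them SULT1A1, a sulfotransferase (0.53 ± 0.09), and UGT1A6 (0.51 ± 0.09). That list's call had a camera adjusted p of 0.00643, and an adjusted p = 0.139 with an estimated correlation. The probe sets of SULT1A1, UGT1A6 and FTL can cross-hybridise, as can those of JUN, HSPA8, HNRNPD and AKR1C1, named below.

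Target genes of p53, the DNA damage-responsive transcription factor, rose in 23 of 33 cases and fell in 1, or 24 and 1 when adjusted over the list alone (camera adjusted p = 3.86e-17). SESN1 rose by 2.32 ± 0.16, TP53INP1 by 2.30 ± 0.14 and ACER2 by 1.77 ± 0.13. MDM2, the ubiquitin ligase that restrains p53, differed by 0.29 ± 0.09 with an adjusted p of 0.0482. It was not called with median centring (0.0872), in a fit of the AF and DMSO arrays only (0.0739), or with replicate blocks (0.0885). Nor was it called without any 1 of the arrays except DMSO replicate 2 (0.0591 to 0.162). The 9 probe sets of MDM2 changed by 0.21 to 0.82, and 3 were called higher and 0 lower when every probe set was tested. Integrated stress response genes rose in 10 of 21 cases and fell in 3, or 11 and 4 when adjusted over the list alone (camera adjusted p = 0.00994 and adjusted p = 0.109 with an estimated correlation). In that list DDIT4 rose by 1.32 ± 0.09 and CEBPG fell by 0.89 ± 0.09. Immediate early genes, the fast transcriptional responders, rose in 9 of 23 cases and fell in 4, or 10 and 5 when adjusted over the list alone (camera adjusted p = 0.0108 and adjusted p = 0.18 with an estimated correlation), with JUN at 1.22 ± 0.08 and KLF4 at 2.09 ± 0.14.

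Mitosis genes fell in 35 of 43 cases and none rose, or 36 falls when adjusted over the list alone (camera adjusted p = 1.55e-20). NDC80, a kinetochore protein gene, fell by 2.31 ± 0.08, AURKA, a mitotic kinase gene, by 1.59 ± 0.09 and CENPF by 1.05 ± 0.08. Homologous recombination and Fanconi anaemia genes fell in 10 of 27 cases and 1 rose, or 11 and 1 when adjusted over the list alone (camera adjusted p = 0.000214). BLM, a helicase gene, fell by 1.37 ± 0.10, BARD1 by 1.61 ± 0.16 and FANCM by 1.71 ± 0.21. Wnt and TGF-beta feedback genes fell in 10 of 19 cases and 1 rose, the same when adjusted over the list alone (camera adjusted p = 0.000214). DKK1, a secreted Wnt inhibitor, fell by 2.02 ± 0.08 and RNF43 by 1.62 ± 0.17. Of 506 zinc finger genes, taken by their symbol, 109 fell and 30 rose, or 117 and 34 when adjusted over the list alone (camera adjusted p = 0.00312 and adjusted p = 0.0548 with an estimated correlation). ZNF644 (-1.88 ± 0.10) and ZNF165 (-2.32 ± 0.14) were among those that fell.

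Respiratory chain genes rose in 18 of 42 cases with no falls, or 26 when adjusted over the list alone (camera adjusted p = 9.21e-08), by small amounts such as 0.52 ± 0.09 for NDUFB8 and 0.43 ± 0.08 for NDUFA2. Of 46 cytosolic ribosomal protein genes RPL23 alone rose (1.25 ± 0.15), also when adjusted over the list alone. The list's mean was 0.10 and its camera adjusted p 0.0348, against an adjusted p = 0.253 with an estimated correlation. That call was also lost when each array was centred on its median (0.06, adjusted p = 0.131) or quantile normalised (0.06, adjusted p = 0.39), with replicate blocks (0.0629), and without DMSO replicate 1 (0.0632), DMSO replicate 3 (0.0593), AF replicate 1 (0.0653) or AF replicate 2 (0.0518). Basal and mesenchymal markers rose in 4 of 18 cases and none fell, or 5 when adjusted over the list alone (camera adjusted p = 0.0198 and adjusted p = 0.0945 with an estimated correlation). They were ACTA2 (2.23 ± 0.22), COL1A1 (1.05 ± 0.28), PDGFRB (0.53 ± 0.15) and CDH2 (0.42 ± 0.11), where PDGFRB and CDH2 had signals under 3.5 in both groups. With every probe set tested, 1 of 3 was called for ACTA2 (-0.01 to 2.23) and 1 of 5 for COL1A1 (-0.08 to 1.05). COL1A1 was not called without DMSO replicate 1, DMSO replicate 2, AF replicate 2 or AF replicate 3 (adjusted p from 0.0552 to 0.079). PDGFRB was not called with replicate blocks or without DMSO replicate 1, 2 or 3 or AF replicate 1 or 2 (0.0558 to 0.0981), nor CDH2 with a trended and robust prior or without DMSO replicate 1 or 3 or AF replicate 1 or 3 (0.055 to 0.0743). None of the 16 measured markers of immune and endothelial cells was called, also when adjusted over the list alone (camera adjusted p = 0.709), and LYZ, with the smallest p of them, differed by 0.20 ± 0.10.

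In all, 4557 genes were called at an adjusted p under 0.05 with AF, 1977 higher and 2580 lower. The balance depended on the scaling, with 2298 higher and 2335 lower after quantile normalisation and 1636 and 2761 after median centring. Among the changes of at least 2-fold, 159 genes were higher and 858 lower, and of at least 4-fold 27 and 95. The 3 AF arrays did not overlap the 3 DMSO arrays for 38.2% of genes, against 10% by chance. The median change over all genes was 0.04, and values were normalised between arrays before deposit, so a shift shared by all transcripts would not be seen.

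**Figure D1:**
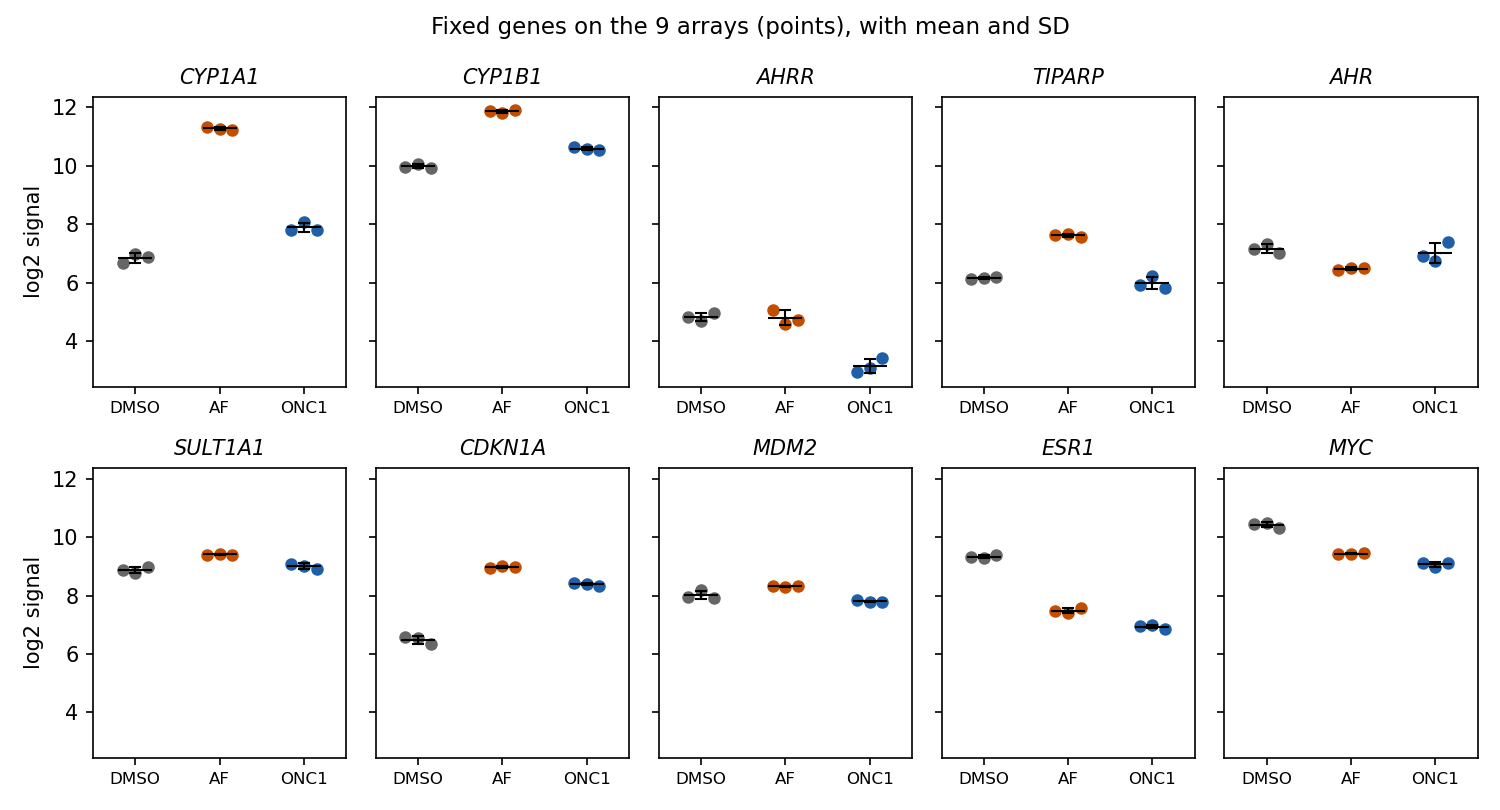
Log2 signal of 10 genes chosen before the data were examined, for the DMSO, AF and ONC1 groups. Points are the 3 arrays of a group, black bars are the mean and SD, and CYP1A1 lies at 6.84 in DMSO, 11.28 with AF and 7.89 with ONC1, and ESR1 at 9.33, 7.48 and 6.94.

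The second comparison asked what 16 h of ONC1 did. Integrated stress response genes, which follow phosphorylation of the translation factor eIF2 alpha, rose in 20 of 21 cases with none falling, the same when adjusted over the list alone (camera adjusted p = 3.13e-18). ATF3 rose by 6.23 ± 0.23 in log2 signal, a lower bound, since its DMSO signal of 3.28 cannot be told from background. NUPR1 was 24.8-fold higher (4.63 ± 0.26), DDIT3, the pro-apoptotic factor CHOP, 12.4-fold (3.64 ± 0.17), STC2 9-fold (3.17 ± 0.10) and ASNS, asparagine synthetase, 4.51-fold (2.17 ± 0.08). Cholesterol synthesis genes rose in 16 of 19 cases with no falls, also over the list alone (camera adjusted p = 1.64e-10). MVD rose by 2.41 ± 0.12, LSS by 1.31 ± 0.10, DHCR7 by 1.14 ± 0.08 and FDPS by 1.04 ± 0.08.

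Other genes named by the ranking rule were PMAIP1, 20.2-fold higher (4.33 ± 0.08), GADD45A (4.17 ± 0.11), FOS (3.92 ± 0.18), the growth factor gene HBEGF (3.85 ± 0.16), the cell cycle inhibitor gene CDKN2B (3.76 ± 0.11), EGR1 (3.37 ± 0.13) and the long noncoding RNA APTR (3.33 ± 0.13). The largest falls were in ADCY9, an adenylate cyclase gene (-3.77 ± 0.22), ZMYND8 (-3.76 ± 0.17), BCL2, the anti-apoptotic gene (-3.74 ± 0.13), SAMTOR (-3.71 ± 0.14), SRGAP1 (-3.67 ± 0.24), TNS3 (-3.66 ± 0.21), ARID5B (-3.54 ± 0.18), RAPGEF6 (-3.54 ± 0.23), TANC2 (-3.53 ± 0.22) and GPHN (-3.40 ± 0.16). Their adjusted p-values were 4.81e-06 or lower. ESR1 fell by 2.39 ± 0.09 and MYC by 1.35 ± 0.08. CYP1A1 was 2.08-fold higher (1.05 ± 0.11), CYP1B1 rose by 0.60 ± 0.08 although another of its probe sets was called lower, and AHRR fell by 1.70 ± 0.16, to 3.14. With ONC1 the lower group's signal was under 3.5 for AHRR, FOS, HBEGF, CDKN2B, APTR, SRGAP1, TNS3 and ARID5B, so their differences are lower bounds in size. TIPARP (-0.17 ± 0.11), AHR (-0.15 ± 0.16), SULT1A1 (0.12 ± 0.09) and MDM2 (-0.23 ± 0.09) were not called. However, TIPARP passed the threshold without ONC1 replicate 2 (-0.28, adjusted p = 0.0444), and SULT1A1 with the mean over its probe sets (0.26, adjusted p = 0.03). MDM2 passed it without the dimmest genes (adjusted p = 0.0469) or with a trended and robust prior (0.0268). Of the 9 MDM2 probe sets, 2 were called lower and 1 higher when every probe set was tested (-0.78 to 0.50).

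Target genes of p53 rose in 22 of 33 cases and fell in 1, or 22 and 4 when adjusted over the list alone (camera adjusted p = 1.68e-06), with CDKN1A at 1.90 ± 0.09 and GDF15 at 2.92 ± 0.08. Immediate early genes rose in 15 of 23 cases and fell in 3, also over the list alone (camera adjusted p = 5.17e-06). Heat shock genes fell in 8 of 14 cases and 1 rose, the same over the list alone (camera adjusted p = 0.00725 and adjusted p = 0.0864 with an estimated correlation). HSPA8, a constitutive chaperone gene, fell by 1.61 ± 0.07, the co-chaperone gene BAG3 by 1.12 ± 0.08 and HSPA1A by 0.86 ± 0.10, while HSF1, the factor that drives such genes, rose by 0.77 ± 0.11. Respiratory chain genes rose in 18 of 42 cases and fell in 3, or 19 and 3 over the list alone (camera adjusted p = 0.00207), with NDUFS7 at 0.86 ± 0.08. Ribosomal protein genes rose in 6 of 46 cases, or 1 when adjusted over the list alone, with a mean of 0.16 (camera adjusted p = 0.000513 and adjusted p = 0.0813 with an estimated correlation).

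DNA replication genes fell in 26 of 40 cases and rose in 4, or 29 and 5 when adjusted over the list alone (camera adjusted p = 1.42e-08). POLE2 fell by 1.71 ± 0.09, POLA1 by 1.37 ± 0.08 and MCM3, of the replicative helicase, by 1.35 ± 0.08. Mitosis genes fell in 32 of 43 cases and rose in 2, or 32 and 3 over the list alone (camera adjusted p = 1.08e-11), with ANLN at -1.74 ± 0.11 and CCNA2, cyclin A2, at -1.75 ± 0.11. Homologous recombination and Fanconi anaemia genes fell in 15 of 27 cases with no rises, also over the list alone (camera adjusted p = 3.11e-06), among them BRIP1 (-1.87 ± 0.09), RAD54B (-1.41 ± 0.13) and ATR (-1.33 ± 0.13). Luminal epithelial genes fell in 10 of 15 cases with no rises, or 12 over the list alone (camera adjusted p = 3.11e-06), with KRT19 at -0.88 ± 0.08 and GATA3 at -0.85 ± 0.08. Oestrogen receptor targets fell in 13 of 25 cases and rose in 4, or 14 and 4 over the list alone (camera adjusted p = 0.00442 and adjusted p = 0.0881 with an estimated correlation). MYBL1 (-2.31 ± 0.14) and CA12 (-1.19 ± 0.08) fell and FHL2 (1.80 ± 0.12) rose. Wnt and TGF-beta feedback genes fell in 10 of 19 cases and rose in 3, also over the list alone (camera adjusted p = 0.00539), with BAMBI at -1.69 ± 0.08 and SKI at -1.14 ± 0.10. Splicing factor genes fell in 19 of 45 cases and rose in 7, or 21 and 9 over the list alone, with SRSF3 at -1.56 ± 0.08 and HNRNPD at -1.43 ± 0.09. The splicing list had a camera adjusted p of 0.043, an adjusted p = 0.0813 with an estimated correlation, and was not called without the dimmest genes (0.17), in a fit of the ONC1 and DMSO arrays only (0.0605), with replicate blocks (0.0619), or without ONC1 replicate 2 (0.074), DMSO replicate 1 (0.0547), DMSO replicate 2 (0.0528) or AF replicate 3 (0.0526). Of the immune and endothelial markers LYZ alone was called (0.43 ± 0.10), at signals under 3.5 in both groups, and it was not when its probe sets were averaged (0.06, adjusted p = 0.781).

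With ONC1 6297 genes were called, 2932 higher and 3365 lower. The majority turned with quantile normalisation, to 3330 higher and 3034 lower, and was 2615 and 3581 with median centring. At 2-fold or more, 551 were higher and 1226 lower, and at 4-fold or more 63 and 196. Arrays of the groups did not overlap for 41.9% of genes, against 10% by chance. The median change over all genes was 0.04.

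**Figure D2:**
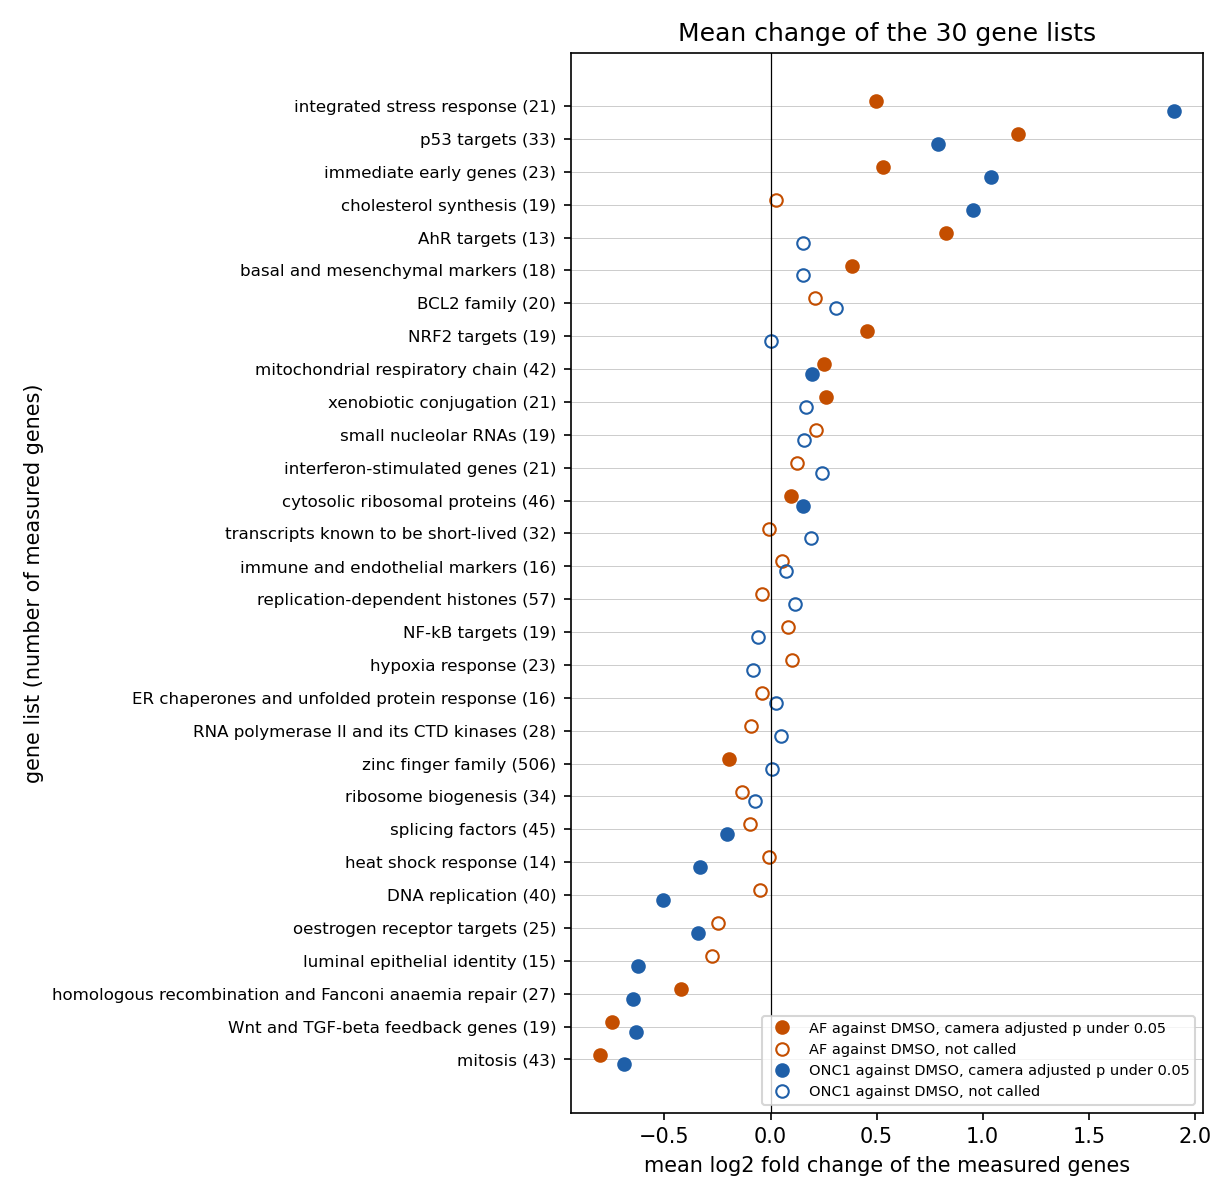
Mean log2 fold change over the measured genes of 30 gene lists, for AF against DMSO (orange) and ONC1 against DMSO (blue). Filled circles mark lists with a camera adjusted p under 0.05 and open circles the others, and integrated stress response genes lie at 0.50 with AF and 1.90 with ONC1, cholesterol synthesis genes at 0.03 and 0.96, and mitosis genes at -0.81 and -0.69.

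The direct comparison of AF with ONC1 sets unlike doses (1 and 5 µM) and times (8 and 16 h) side by side, so a difference can belong to the compound, the dose or the time. SERPINB5 was higher with AF by 3.65 ± 0.12 on the log2 scale, and CYP1A1 was 10.5-fold higher (3.39 ± 0.11). CYP1A2, another AhR-induced P450 whose probe set can cross-hybridise, was higher with AF by 2.61 ± 0.18, ALDH1A3, an aldehyde dehydrogenase gene, by 2.45 ± 0.12, SCFD2 by 2.38 ± 0.09 and POF1B by 2.32 ± 0.33. NUPR1 (-3.29 ± 0.26), DDIT3 (-3.23 ± 0.17), the mitochondrial enzyme gene PCK2 (-2.71 ± 0.12), INHBE (-2.70 ± 0.29), TUBE1 (-3.19 ± 0.11) and KRTAP5-AS1 (-3.25 ± 0.19) were lower with AF than with ONC1. The AF signals of INHBE, TUBE1 and KRTAP5-AS1 and the ONC1 signal of ACER2 were under 3.5, so the differences of these genes are lower bounds in size.

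Integrated stress response genes were lower with AF in 20 of 21 cases, or 21 when adjusted over the list alone (camera adjusted p = 6.02e-22), with CEBPG at -2.33 ± 0.09, ASNS at -1.81 ± 0.08 and CEBPB at -1.56 ± 0.08. Cholesterol synthesis genes were lower with AF in 17 of 19 cases, or 18 over the list alone (camera adjusted p = 2.1e-15), with MVD at -2.26 ± 0.12 and HMGCS1 at -1.10 ± 0.09. Immediate early genes were lower with AF in 13 of 23 cases and higher in 3, or 14 and 4 over the list alone (camera adjusted p = 0.000686 and adjusted p = 0.084 with an estimated correlation). FOS was among them (-2.32 ± 0.18). Zinc finger genes were lower with AF in 100 of 506 cases and higher in 8, also over the list alone (camera adjusted p = 0.000201), with ZNF140 at -1.62 ± 0.10.

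DNA replication genes were higher with AF than with ONC1 in 27 of 40 cases and lower in 3, or 28 and 3 over the list alone (camera adjusted p = 1.13e-11), with MCM3 at 1.21 ± 0.08 and PCNA at 0.89 ± 0.08. NRF2 targets were higher with AF in 15 of 19 cases and lower in 1, also over the list alone (camera adjusted p = 2.42e-06), where AKR1C1 differed by 1.35 ± 0.12 and SLC7A11 by -1.35 ± 0.12. Target genes of p53 were higher with AF in 16 of 33 cases and lower in 6, or 17 and 6 over the list alone (camera adjusted p = 0.000318). ACER2 differed by 1.73 ± 0.13 and RRM2B, a ribonucleotide reductase subunit gene, by 0.89 ± 0.09. AhR targets were higher with AF in 7 of 13 cases and lower in 2, also over the list alone (camera adjusted p = 0.00531 and adjusted p = 0.0834 with an estimated correlation). Heat shock genes were higher with AF in 6 of 14 cases and lower in 1, or 7 and 1 over the list alone, luminal genes in 9 of 15 and 1, or 10 and 1 over the list alone, and homologous recombination and Fanconi anaemia genes in 8 of 27 and 2, or 11 and 3. Their camera adjusted p-values were 0.000686, 0.000324 and 0.00901, and each had an adjusted p = 0.0548 with an estimated correlation. In all, 4138 genes differed between the compounds, 2101 higher and 2037 lower with AF, and 352 and 340 by at least 2-fold. This near-even split turned to 1935 higher and 2212 lower with quantile normalisation. It also turned in a fit of the AF and ONC1 arrays only (1723 and 1738), at an adjusted p under 0.01 (1235 and 1255), and without AF replicate 2 (1652 and 1657), ONC1 replicate 1 (1756 and 1773) or ONC1 replicate 2 (1768 and 1913).

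The responses to AF and ONC1 were also set side by side. Both compounds raised ATF3, GADD45A, PMAIP1, NEAT1 and GDF15, and both lowered ARID5B, SAMTOR, RAPGEF6, SRGAP1 and CHST15, the genes with the largest changes shared by the 2 comparisons. In the direct comparison NEAT1, not called, differed by 0.02 ± 0.16 and CHST15, also not called, by 0.22 ± 0.15, with 95% intervals of -0.34 to 0.38 and -0.13 to 0.56. SRGAP1 and RAPGEF6 were called only without AF replicate 2 (0.84, adjusted p = 0.00789, and 0.54, adjusted p = 0.0427). GDF15 was called only with a trended and robust prior (0.18, adjusted p = 0.0263). GADD45A was called lower with AF, but not with replicate blocks (-0.41, adjusted p = 0.0556). Nor was it called without AF replicate 1, 2 or 3 or ONC1 replicate 1 or 2 (adjusted p from 0.0577 to 0.0932). Of all genes, 3187 were called in the same direction, 1258 higher and 1929 lower. Independent lists of these sizes, drawn from all genes with those near background included, would share 732.2 genes. The 100 simulated pairs of unchanged groups set against the shared DMSO arrays shared 0 genes at most. With no gene changed in those draws, hardly any could be called, so that count cannot show what shared controls add to the overlap. Among the shared genes, 780 differed in size with the larger change under ONC1 and 255 with the larger under AF. The log2 fold changes correlated with r = 0.722 across genes, which are not independent replicates, against a median of 0.5002 in the simulated pairs. Their covariance was 0.202, against 0.0113. With 3 DMSO arrays the controls could not be split into 2 parts of 2, so the correlation includes a part from the shared controls, and the overlap may.

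**Figure D3:**
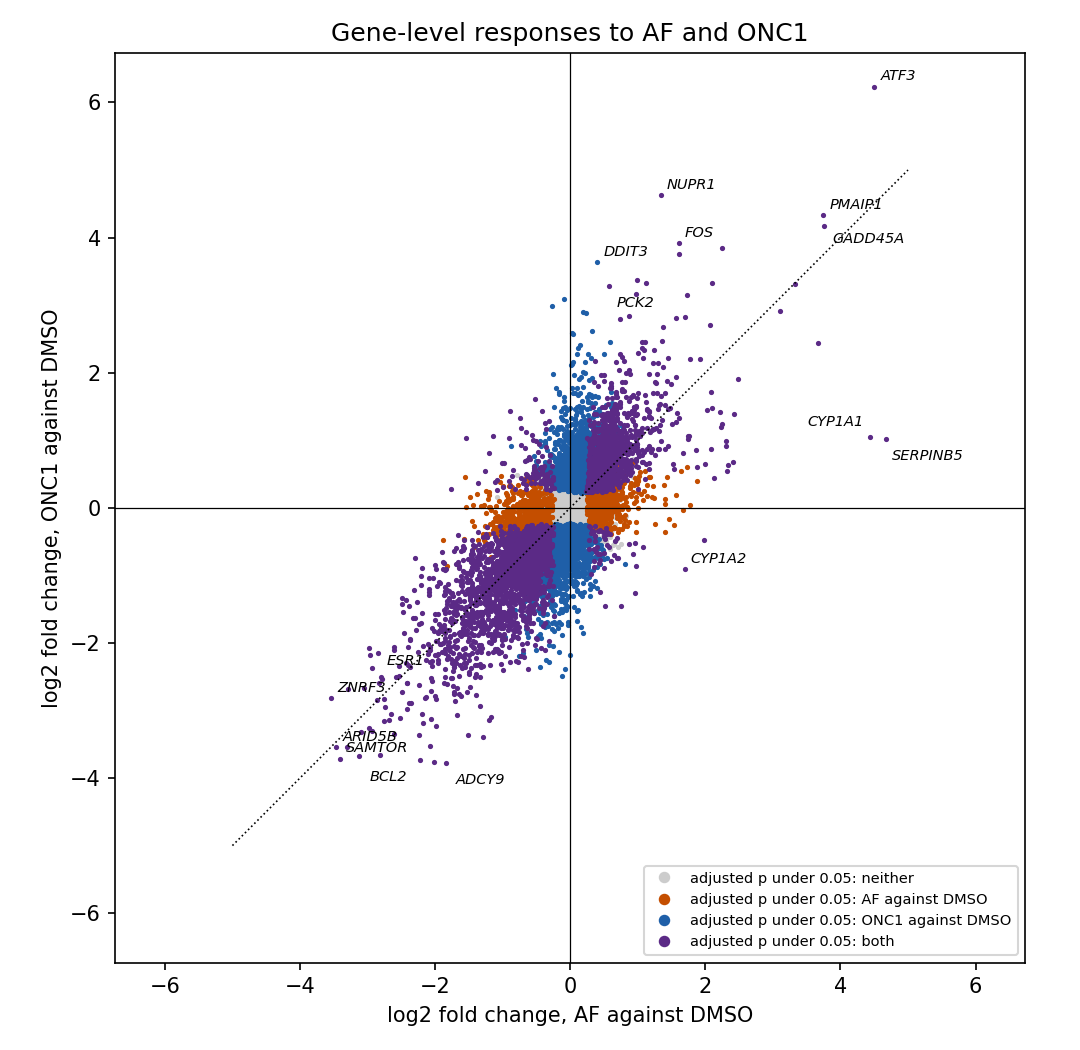
Log2 fold change of each of 19774 genes with ONC1 (vertical axis) against that with AF (horizontal axis), coloured by which comparison with DMSO called the gene. The dotted line marks equal change, CYP1A1 lies far to the right (4.44) at 1.05 on the vertical axis, SERPINB5, with a DMSO signal near background, at 4.67 and 1.02 or more, and DDIT3 lies at 0.40 and 3.64.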

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

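The tests of shared DMSO arrays and of dose and exposure time, and the alternatives for genes that AF and ONC1 changed in opposite directions, were chosen after the result was seen. The 6 genes named for those opposite changes were also chosen after their values were seen.

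AF and ONC1 changed 151 genes in opposite directions. All 151 differed in the direct comparison, which largely follows from their selection and is no separate support. For opposite changes in the same fit, the direct difference is larger than either change. The count fell to 97 without DMSO replicate 1, 83 without DMSO replicate 2 and 79 without DMSO replicate 3, was 233 without the dimmest genes and 287 with a trended and robust prior, and was 47 at an adjusted p under 0.01 and 2 when both changes had to be at least 2-fold. VEGFA, which encodes an angiogenic growth factor, fell by 0.91 ± 0.10 with AF and rose by 1.04 ± 0.10 with ONC1 (log2, SE, n = 3 arrays per group), IFRD1 changed by -1.55 ± 0.13 and 1.04 ± 0.13, CEBPG by -0.89 ± 0.09 and 1.44 ± 0.09, and CYP1A2 by 1.69 ± 0.18 and -0.91 ± 0.18. EGLN3, an oxygen-sensing hydroxylase gene, changed by 0.96 ± 0.16 and -1.26 ± 0.16 and ZNF473 by -1.14 ± 0.20, a lower bound in size since its AF signal was under 3.5, and 1.06 ± 0.20. With the mean over its probe sets EGLN3 was not called with AF (0.32, adjusted p = 0.166), nor ZNF473 with ONC1 (0.36, adjusted p = 0.0652). Of the 4 VEGFA probe sets, 1 was called lower with AF and 0 higher when every probe set was tested (-0.91 to -0.24).

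Of 30 gene lists, 11 responded differently to AF and to ONC1 in the direct comparison, and 6 of these held with an estimated correlation. The largest mean differences among the lists higher with ONC1 were in integrated stress response and cholesterol synthesis genes. Integrated stress response genes had a mean difference of -1.41 and array means, relative to DMSO, of 0.47 to 0.52 with AF and 1.87 to 1.94 with ONC1. Cholesterol synthesis genes had a mean difference of -0.93 and array means of -0.02 to 0.07 and 0.95 to 0.97. A single array as the whole source is argued against, since both lists stayed called without each of the 9 arrays in turn, and the mean difference nearest to 0 was -0.902, of cholesterol synthesis genes without AF replicate 3. The DMSO arrays cancel out of this difference, so only leaving out an AF or ONC1 array could test it. The dose and exposure time cannot be told apart from the compound, because 0 AF and ONC1 arrays shared a dose and a time, and a biological difference between the compounds stays open.

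AF and ONC1 changed 3187 genes the same way. Shared DMSO arrays give 2 comparisons a common error and may add to such an overlap. Random error of those arrays as the whole source is argued against by the covariance of the log2 fold changes. That covariance was 17.1 times the highest of the simulated unchanged groups. An offset common to the DMSO arrays, such as one from their unstated exposure time, was not simulated and stays open. How much of the overlap belongs to responses common to many toxic exposures stays open and was not tested.

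Probe sets without a single gene name numbered 13699 and were not used in the comparisons of genes. When every probe set was tested, 955 of them were called with AF and 1516 with ONC1, 6.97% and 11.1%, against 17.1% and 25.3% of the named probe sets.

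The 6 arrays of each comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05, since the smallest share is 0.1. In each comparison 1 of the splits, the real one, gave as many genes. The real splits called 4557 genes for AF against DMSO, 6297 for ONC1 against DMSO and 4138 for AF against ONC1. The highest of the other splits called 0 with limma. Every other split mixes arrays of both groups, so the difference between the groups enters the spread, and that 0 cannot measure chance.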

How the results depend on the processing

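The alternatives for genes changed in opposite directions were chosen after the data were seen. Of 38 list calls 22, and of 378 calls of named genes 317, kept their direction and side of the threshold under every alternative applied to them. Named genes were not put to the 2-fold minimum, the adjusted p under 0.01 or the test of every probe set. Lists were not put to the 2-fold minimum, the test of every probe set or the trended and robust prior. With every probe set tested, 7934 probe sets were called for AF, 11870 for ONC1, 7059 for AF against ONC1 and 5479 the same way by both, as more were tested. At an adjusted p under 0.01 the counts were 2822 for AF, 2490 for AF against ONC1 and 1985 the same way, and at 2-fold or more 1017 for AF, 1777 for ONC1, 692 for AF against ONC1 and 698 the same way, by construction. The 151 genes changed in opposite directions became 233 without the dimmest genes, 287 with a trended and robust prior, 47 at an adjusted p under 0.01, 2 at 2-fold or more, and 79 to 138 without each array in turn. Without each array the counts were 3511 to 4628 for AF, 5326 to 6136 for ONC1, 3309 to 3915 for AF against ONC1 and 2479 to 3034 the same way. The correlation of the fold changes was 0.704 with the mean over probe sets and 0.707 to 0.733 without each array. Lists called fell to 6 for AF and 6 for AF against ONC1 with an estimated correlation, rose to 23, 25 and 23 with fry, which tests another question, and to 17 for AF against ONC1 with the mean over probe sets. Transcripts known to be short-lived with ONC1 had a mean of 0.19 and were called higher by fry (adjusted p = 0.000178), against a direction of Down with camera. Except where the construction shows it, the cause was not tested.

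With replicate blocks 4060 genes were called for AF, 5891 for ONC1, 3657 for AF against ONC1, 2845 the same way and 102 in opposite directions. Differences between the compounds in BCL2, CDKN1A, ESR1 and MYC were not called with the mean over probe sets (0.42, 0.28, 0.28 and 0.12, adjusted p from 0.0521 to 0.603). For CDKN1A that mean takes in another probe set, which changed by only 0.09 with AF and 0.11 with ONC1. For the other genes the cause was not tested. The number of arrays limits the precision, and a signal near the arrays' lower end cannot be told from background without detection calls.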

Other observations

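No test in the paragraphs on gene groups was chosen after the result was seen.

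The gene groups that camera did not call held genes with sizeable changes. In the BCL2 family, AF raised 3 of 20 measured genes and lowered 1, or 6 and 4 when adjusted over the list alone (camera adjusted p = 0.164), and ONC1 raised 7 and lowered 2, also over the list alone (0.0741). PMAIP1 rose with both compounds, BCL2 fell with both (-2.22 ± 0.13 with AF and -3.74 ± 0.13 with ONC1), BAX, a pore-forming protein gene, rose with AF by 0.78 ± 0.10, and HRK rose with ONC1 by 2.16 ± 0.21. With quantile normalisation the BCL2 family was called with ONC1 (0.40, adjusted p = 0.0195). Among the genes of RNA polymerase II and its CTD kinases, AF raised 6 of 28 and lowered 7, or 8 and 7 over the list alone, and ONC1 raised 11 and lowered 7, or 13 and 7 (camera adjusted p = 0.75 and 0.412). CCNT2, a cyclin gene of the elongation kinase P-TEFb, changed by -1.79 ± 0.24 with AF and -1.67 ± 0.24 with ONC1, and POLR2A, the largest subunit gene, by 0.40 ± 0.09 and 1.02 ± 0.09. That list with AF had a mean of -0.09, a median of 0.11 and a camera direction of Up. Replication-dependent histones rose in 5 of 57 cases and fell in 6 with AF, and rose in 14 and fell in 4 with ONC1, the same over the list alone (camera adjusted p = 0.844 and 0.172). The linker histone gene H1-3 fell by 2.84 ± 0.21 with AF and 2.14 ± 0.21 with ONC1, while H2AC17 rose with ONC1 by 1.34 ± 0.18. The histone list with AF had a mean of -0.04 and a median of 0.05. Hypoxia response genes rose in 8 of 23 cases and fell in 4 with AF, or 8 and 5 over the list alone, and rose in 5 and fell in 5 with ONC1, or 6 and 6 (camera adjusted p = 0.358 and 0.736). SLC2A1, the glucose transporter gene GLUT1, fell by 1.23 ± 0.12 with ONC1. Interferon-stimulated genes rose in 5 of 21 cases and fell in 1 with each compound, also over the list alone (camera adjusted p = 0.373 and 0.274), with ISG20, an exonuclease gene, at 0.68 ± 0.15 with AF and 2.16 ± 0.15 with ONC1. NF-kB targets rose in 1 of 19 cases with AF, SOD2 (0.60 ± 0.10), and rose in 1 and fell in 3 with ONC1, with NFKBIA at -0.80 ± 0.11, all also over the list alone (camera adjusted p = 0.447 and 0.792). Small nucleolar RNAs rose in 3 of 19 cases with AF, and rose in 2 and fell in 1 with ONC1, also over the list alone (camera adjusted p = 0.171 and 0.707), with SNORA28 at 1.30 ± 0.20 and 2.14 ± 0.20.

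Some groups passed camera's threshold with one compound or with neither. ER chaperones and unfolded protein response genes rose in 2 of 16 cases and fell in 4 with AF, or 5 and 5 over the list alone, and rose in 6 and fell in 5 with ONC1, also over the list alone (camera adjusted p = 0.882 and 0.96). With AF this list had a mean of -0.04 and a median of 0.04, and with ONC1 a mean of 0.02 and a median of -0.05. XBP1, a transcription factor gene of the unfolded protein response, fell by 0.67 ± 0.10 with AF. Transcripts known to be short-lived rose in 5 of 32 cases and fell in 10 with AF, or 5 and 12 over the list alone, and rose in 11 and fell in 10 with ONC1, or 11 and 13 (camera adjusted p = 0.256 and 0.96). The short-lived list with ONC1 had a mean of 0.19, a median of -0.05 and a camera direction of Down, and CDC25A, a cell cycle phosphatase gene, fell by 1.37 ± 0.11 with AF and 1.68 ± 0.11 with ONC1. Ribosome biogenesis genes fell in 7 of 34 cases with AF, also over the list alone, and rose in 6 and fell in 9 with ONC1, or 7 and 11 (camera adjusted p = 0.159 and 0.47), with UTP20 at -0.60 ± 0.10 and -1.63 ± 0.10. AF lowered 9 of 25 oestrogen receptor targets and raised 4 (camera adjusted p = 0.159). RARA, a retinoic acid receptor gene among them, changed by -2.43 ± 0.14, but only 1 of its 5 probe sets was called (-2.43 to -0.14). AF also lowered 4 of 15 luminal genes and raised 2 (0.136), with GATA3 at -1.44 ± 0.08, 10 of 40 DNA replication genes with 5 raised (0.447), 9 of 45 splicing factor genes with 4 raised (0.358), 3 of 14 heat shock genes with 1 raised (0.74) and 2 of 19 cholesterol synthesis genes with 5 raised (0.709). Over the list alone these counts were 9 and 4, 6 and 3, 11 and 9, 12 and 5, 3 and 1, and 2 and 5. ONC1 raised 3 of 13 AhR targets and lowered 2 (camera adjusted p = 0.736), 4 of 19 NRF2 targets and lowered 6 (0.437), 2 of 18 basal and mesenchymal markers (0.495), 3 of 21 xenobiotic conjugation genes and lowered 3 (0.356), 82 of 506 zinc finger genes and lowered 84 (0.868), and 1 of 16 immune and endothelial markers (0.602). Over the list alone 5 NRF2 targets were higher and 8 lower, 82 zinc finger genes higher and 87 lower, and the others had the same counts.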
